A study of Mus musculus with 20 samples.

How the data were processed

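RNA was measured in epididymal fat of male C57BL6/J mice, a common inbred laboratory strain, kept on chow (day 0) or switched to a high-fat diet for 2, 4, 6 or 14 days. Per the labels, total RNA was isolated with a column kit and sequencing libraries were made with Illumina's TruSeq RNA kit. Each of the 5 groups held 4 libraries, 20 in all, which the labels call biological replicates. The deposited table holds raw counts of reads per gene for 39179 Ensembl gene IDs, as whole numbers with 1 column per library. The submitters' processing notes name CASAVA, STAR, featureCounts, limma and R (version 3.0) without saying what each was used for. They state no genome build, annotation or strand setting, so no coordinates are given, and reads from a gene and an overlapping or antisense partner cannot be told apart. Reads of near-identical family members, such as Mup or Serpina1 genes and pseudogenes like Cd63-ps, could likewise be split between copies, so their values are uncertain.

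Gene symbols were looked up by Ensembl ID in a reference table of names. A symbol was found for 37607 IDs, and the IDs without one held 0.139% of all counts. All columns were matched to samples by the library names in the labels. The analysis started from the counts as deposited, in R 4.3.3. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15, by group), which left 15254 genes, 141 of them without a symbol. At least 99.5% of the counts of each library fell on these genes. Library totals were scaled with TMM factors. Levels are given as CPM, the counts scaled to TMM-adjusted library totals, and means have an SD over 4 libraries.

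Differences were tested with edgeR 4.0.16 by the quasi-likelihood F test with robust dispersion. A single fit held all 20 libraries with the group as its only term and 15 residual degrees of freedom, and the common biological coefficient of variation was 0.209. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, separately for each comparison, and a gene was called at an adjusted p under 0.05. Standard errors of log2 changes were derived from the F statistic. Each high-fat day was compared with day 0, later days with earlier ones (4 with 2, 6 with 4, 14 with 6 and 14 with 2), and all 5 groups with each other in a test of any difference.

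The comparisons, tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. The 42 lists cover metabolic, signalling, stress and immune pathways, markers of adipocytes and of other cell types that the fat pad or a neighbouring organ could contribute, and signs of RNA quality. Lists with at least 5 measured genes (41 of them) were tested against all other genes with camera in limma 3.58.1, on TMM log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera was run again with the correlation estimated from the data. The fry test, which asks whether a list's genes move on balance in 1 direction, was an alternative. List p-values were adjusted by the Benjamini-Hochberg method within each comparison. Members were counted by their call over all genes, and also after adjustment over the list alone.

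Named genes followed a rule. For each comparison with day 0 it took the 6 largest rises and the 6 largest falls among called genes with a mean of at least 1 CPM and no overlap between the compared libraries, passing over clone names. From each list it took up to 4 called members with the smallest adjusted p or, with none called, up to 2 with the highest expression. A panel of 23 genes was taken whatever their p, as were the 4 largest rises and falls between high-fat days and the 10 smallest p of the test of any difference.

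Alternatives were DESeq2 size factors (RLE) in the edgeR fit, scaling by library size only, no filter, and a stricter filter (at least 1 CPM in 4 libraries and a mean of 2 CPM). Further ones were DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit of only the groups compared, the replicate number as a term, and the library number as a covariate. The threshold was also moved to 0.01 or joined with an absolute log2 change above 1, the prior count for the lists to 0.5, and each library was left out in turn. An adjusted p that DESeq2 gave as missing was left missing. Comparisons with the same chow libraries were set beside 20 simulated sets of unchanged groups and beside fits with the controls split 2 and 2. For each pair of groups all 35 splits of the 8 libraries were refitted, and 100 drawn splits for the test of any difference. Where a group had at most 3 reads of a gene, no fitted change is given. With 0 reads the fold is a lower bound at a floor of 3 counts over the group, and with 1 to 3 reads the ratio has a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

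The steps were tested on simulated counts with the real means and library sizes and a set of genes changed 1.5-, 2- or 4-fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery at lower levels was not tested. Counts were drawn for each gene on its own, so no simulated library stood apart as a whole. Of genes changed 2-fold, 62.9% were recovered on day 2, 73.5% on day 4, 63.2% on day 6 and 74.2% on day 14, with 6, 8, 7 and 4 false calls. Of genes changed 1.5-fold, 41.9%, 38.2%, 42.2% and 46.6% were recovered on the same days.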

Results

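Gene expression in epididymal fat was measured in 4 libraries from mice on chow and in 4 libraries each after 2, 4, 6 and 14 days of high-fat feeding. The total counts per library ranged from 1916829 to 38832429, a 20.3-fold span. Totals were 8279454 to 38832429 on day 0, 1916829 to 26798901 on day 2 and 4578703 to 16274913 on day 4. They were 11418864 to 32363044 on day 6 and 6724707 to 24581101 on day 14. Scd1, which encodes a fatty acid desaturase, held 4.75% of all counts, ahead of the carbonic anhydrase gene Car3 with 2.04% and the mitochondrial gene mt-Co1 with 1.85%. Log2 CPM correlated across genes at 0.954 to 0.989 between libraries of the same group, where genes are not independent replicates. Chow replicate 4 stood apart from the other chow libraries by genes known from ductal epithelium, with 80.1 CPM of the epididymal and pancreatic gene Cuzd1 against 0 to 0.116 CPM. The tissue they came from was not settled. Day 2 replicate 1 had the smallest total. Counts without these 2 doubted libraries are given beside the main ones, as an alternative chosen after seeing the data. Day 4 replicate 1 and day 6 replicate 4, which also stood apart from their groups, stayed in that alternative. No fit left those libraries out together. Scaling by library size only moved the median log2 change of all genes to -0.14 on day 2, -0.13 on day 4, -0.14 on day 6 and -0.10 on day 14, and changes below are relative to the TMM scale.

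After 2 days, Mest, an imprinted gene whose expression rises in enlarging fat, climbed from 85.7 ± 16.6 CPM on chow to 447 ± 139 CPM (SD, n = 4). Its log2 change was 2.37 ± 0.38 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00578). Trarg1, a protein of insulin-responsive glucose transporter vesicles, rose by 1.05 ± 0.12 (log2, SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00097). Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.04 ± 0.16, and the growth factor gene Fgf1 fell by 0.85 ± 0.12. In total 670 of 15254 genes differed from chow, 371 higher and 299 lower, and with scaling by library size only 821 differed, 228 higher and 593 lower. The largest rises were Bpifb6 (3.30 ± 0.79), Serpina1d (2.50 ± 0.54) and Mest, followed by Paqr9 (2.33 ± 0.39), Pla2g2e (2.12 ± 0.51) and Efcab8 (1.85 ± 0.42). The largest falls were Atp6v0a4 (-4.33 ± 0.87), the endocytic receptor Lrp2 (-3.82 ± 0.88), AW551984 (-3.65 ± 0.82), Nme5 (-3.41 ± 0.90), the matrix glycoprotein Thbs1 (-3.25 ± 0.81) and the tight junction gene Cldn1 (-2.79 ± 0.76). Lrp2 measured 194 CPM in chow replicate 4 against 8.03 to 15.6 CPM in the other chow libraries. Nme5 measured 9.10 against 0.465 to 0.640 CPM, and had an adjusted p = 0.240 without that library in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Each of these rises and falls other than Mest and Paqr9 was lost in at least 2 of the 8 fits without 1 library.

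Markers of mesothelium, the cell layer that covers the fat pad, formed the list with the most falls on day 2. Of 18 measured genes 16 fell and none rose (17 fell when adjusted over the list alone), with a median log2 change of -1.32. Msln fell by 2.10 ± 0.41, Lrrn4 by 1.75 ± 0.33, Upk3b by 1.56 ± 0.30 and Rspo1 by 1.28 ± 0.25. Camera gave this list a Benjamini-Hochberg adjusted p = 5.33e-12, with adjusted p = 0.679 with an estimated correlation and 0.00822 by fry. The median stayed negative under every scaling, but library size only lowered changes in general and could not have turned it. The number called was 6 without chow replicate 4, 0 without day 2 replicate 4 (Msln then had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0579) and 0 without both doubted libraries.

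Genes of mitochondrial energy metabolism lay higher on day 2. All 62 oxidative phosphorylation genes had a positive change, and 6 rose, among them Cox5b (0.48 ± 0.12) and Atp5g3 (0.69 ± 0.18), or 25 when adjusted over the list alone. Of 22 citrate cycle genes 2 rose, Mdh2 (0.62 ± 0.15) and Idh3a (0.86 ± 0.21), or 14 when adjusted over the list alone. Of 25 fatty acid oxidation genes Cpt1a, Cpt2 (0.84 ± 0.17) and Acads (0.58 ± 0.13) rose, and 12 rose and 2 fell when adjusted over the list alone. Of 22 genes of lipolysis and the lipid droplet 6 rose, or 12 when adjusted over the list alone, including the lipase gene Mgll (0.55 ± 0.14) and Plin5 (0.86 ± 0.22). Of 25 genes of cholesterol synthesis and uptake 5 rose, by either adjustment, including Insig1 (2.12 ± 0.48) and Hmgcs1 (1.28 ± 0.33). The cholesterol list mean was -0.06 in day 2 replicate 2 against 0.87 to 1.24 in the rest of that day, and 0.59 in chow replicate 1 against -0.37 to -0.10 in the other chow libraries. By camera the Benjamini-Hochberg adjusted p of these 5 lists were 4.98e-15, 1.24e-07, 8.36e-06, 1.64e-04 and 1.37e-07, each with adjusted p = 0.679 with an estimated correlation. Their medians stayed positive under every scaling, from 0.20 to 0.63 with library size only. None of these list members other than Cpt1a kept its call without chow replicate 4, and none at all without both doubted libraries. The medians of the 5 lists, in the order given, were 0.31, 0.33, 0.33, 0.41 and 0.75 with all libraries. Without both doubted libraries they were 0.27, 0.31, 0.28, 0.36 and 0.59. Mitochondrially encoded RNA also lay higher, in 13 of 15, with a median of 0.23 and 0 called members by edgeR over all genes, or 2 that rose when adjusted over the list alone. Of 69 ribosomal protein genes 9 had a positive change, with a median of -0.11 and 0 called by either adjustment. Camera gave these 2 lists Benjamini-Hochberg adjusted p = 0.0130 and 6.31e-04, each with adjusted p = 0.679 with an estimated correlation.

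Macrophage genes, all 24 with a negative change on day 2, included no called member. The most expressed were Lyz2 (-0.58 ± 0.22; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.112) and Retnla (-0.13 ± 0.24). The macrophage list had a camera Benjamini-Hochberg adjusted p = 4.13e-04, with adjusted p = 0.679 with an estimated correlation and 0.174 by fry. Camera placed 14 lists past the threshold on day 2, and none passed with an estimated correlation. The count of 670 genes was 43 without day 2 replicate 4, 71 without day 2 replicate 1, 92 without chow replicate 2, 98 without chow replicate 4, 323 without day 2 replicate 3, 408 without chow replicate 3, 1549 without chow replicate 1 and 1779 without day 2 replicate 2. It was 8 without both doubted libraries. Of 70 named genes with a call, Mest, Paqr9, Trarg1, Fgf1, Cpt1a, Zfp423, Loxl1 and Ramp2 kept it whichever single library was left out. The other 62 lost it at least once (highest edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.269).

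**Figure D1:**
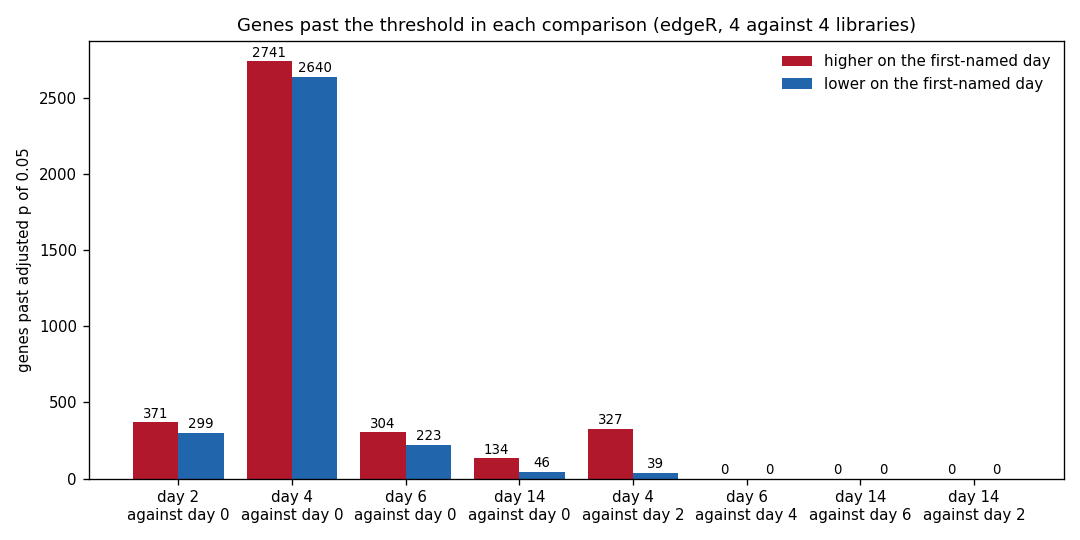
Number of genes past a Benjamini-Hochberg adjusted p of 0.05 (vertical axis, genes) in each pairwise comparison (horizontal axis, 4 against 4 libraries, edgeR), with red bars for genes higher and blue bars for genes lower on the first-named day. Day 4 against day 0 has 2741 higher and 2640 lower genes, and day 14 against day 0 has 134 and 46.

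After 4 days, genes of the cell cycle rose together: all 42 measured members were called higher, by either adjustment, with a median log2 change of 3.11. Ccna2, the cyclin of DNA replication and mitotic entry, went from 1.97 ± 0.768 to 34.7 ± 20.9 CPM (SD, n = 4), a log2 change of 4.03 ± 0.72 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00125). Foxm1, a transcription factor of dividing cells, rose by 3.61 ± 0.62, Uhrf1 by 3.30 ± 0.54 and the mitotic kinase gene Aurkb by 3.12 ± 0.54. Camera gave the list a Benjamini-Hochberg adjusted p = 2.17e-18, with adjusted p = 0.844 with an estimated correlation and 0.00342 by fry. Day 4 replicate 1 stood apart: its mean over the list was 0.59 above chow on the log2 scale, against 3.06 to 3.28 in the other 3 libraries of the day. At least 40 of the 42 genes kept their call whichever library was left out, and 41 did without both doubted libraries.

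Cholesterol genes followed on day 4, with 22 of 25 called higher and none lower (24 higher when adjusted over the list alone). Insig1, a sterol-responsive regulator, rose by 2.85 ± 0.49 and the synthesis gene Msmo1 by 1.21 ± 0.24. Of 48 extracellular matrix genes 28 rose and 3 fell (29 and 3 when adjusted over the list alone), led by Col6a3 (1.92 ± 0.32), Col6a2 (1.78 ± 0.29), Col4a2 (1.36 ± 0.23) and Col5a1 (1.21 ± 0.20). Day 4 replicate 1 had a matrix mean of 0.05 above chow on the log2 scale, against 0.50 to 0.96 in the other 3 libraries of the day. By camera these lists had Benjamini-Hochberg adjusted p = 7.95e-10 and 1.15e-05, with adjusted p = 0.844 and adjusted p = 0.898 with an estimated correlation and 0.00509 and 0.0149 by fry. Of the cholesterol genes 18 were called without day 4 replicate 4. Among 20 endothelial genes 8 rose, by either adjustment, including Ramp2 (1.24 ± 0.16), Egfl7 (0.84 ± 0.18) and Kdr (0.65 ± 0.16). Camera gave the endothelial list a Benjamini-Hochberg adjusted p = 0.00453, with adjusted p = 0.898 with an estimated correlation, and 5 members were called without chow replicate 4. The endothelial mean was -0.03 in day 4 replicate 1 and 0.43 to 0.70 in the rest of the day.

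Mesothelial markers were low on day 4 as well: 17 of 18 fell and Igfbp5 alone rose, by either adjustment, with a median of -1.72. Rspo1 fell by 1.88 ± 0.26, Krt19 by 1.88 ± 0.32, Lrrn4 by 1.90 ± 0.33 and Upk1b by 1.75 ± 0.29, and all 18 calls remained whichever library was left out and without both doubted libraries. Camera gave a Benjamini-Hochberg adjusted p = 2.49e-09, with adjusted p = 0.683 with an estimated correlation and 6.01e-04 by fry. Of 69 genes of cytosolic ribosomal proteins 22 fell and 1 rose, by either adjustment, with Rps27 at -0.72 ± 0.11 and Rpl22 at -0.39 ± 0.08 (camera, Benjamini-Hochberg adjusted p = 1.03e-04, with adjusted p = 0.898 with an estimated correlation). Of 24 genes of T and NK cells 4 fell, including Tcf7 (-2.40 ± 0.64), or 2 when adjusted over the list alone, and 1 was called without day 4 replicate 4. Camera gave the T and NK list a Benjamini-Hochberg adjusted p = 0.0179, with adjusted p = 0.898 with an estimated correlation. Tcf7 had an adjusted p = 0.0574 without chow replicate 4 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Oxidative phosphorylation genes had a median of 0.11 with 4 of 62 called higher (1 when adjusted over the list alone), while scaling by library size only gave a median of 0.00 with 2 higher and 5 lower. Camera gave them a Benjamini-Hochberg adjusted p of 0.0373, or adjusted p = 0.918 with an estimated correlation.

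In total 5381 genes, 35.3% of those tested, differed between day 4 and day 0, 2741 higher and 2640 lower. With scaling by library size only 5431 differed, 1750 higher and 3681 lower. The largest rises were the choline transporter gene Slc5a7 (4.90 ± 0.88), Bpifb6 (4.90 ± 0.78), Pimreg (4.59 ± 0.80), Grid1 (4.59 ± 0.94), Tph2 (4.56 ± 0.86), which encodes a serotonin synthesis enzyme, and Kif18b (4.52 ± 0.89). Among falls, Fermt1 had 0 reads on day 4 and was at least 143-fold lower at a floor of 3 counts over the group, and Slc44a4 had 1 read and a ratio of 228 (95% counting interval 40.7 to 9018). Further falls were Ppp1r1b (-6.44 ± 1.69), the retinoic acid hydroxylase gene Cyp26b1 (-5.47 ± 1.14), Ptgds (-5.40 ± 1.27) and Egfl6 (-5.35 ± 1.22). Fermt1 measured 32.1 CPM in chow replicate 4 and at most 0.349 CPM in the other chow libraries, and Ppp1r1b 35.02 CPM and at most 0.557 CPM. Without that library Fermt1 had an adjusted p = 0.144 and Ppp1r1b an adjusted p = 0.156 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of 5 epididymis genes 4 fell, by either adjustment, and 1 was called without chow replicate 4. Cuzd1 had 0 reads on day 4, at least 355-fold lower at that floor, and an adjusted p = 0.626 without chow replicate 4 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The total was 3225 without day 4 replicate 4 and 3977 without both doubted libraries, and 121 of 159 named genes kept their call whichever library was left out.

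**Figure D2:**
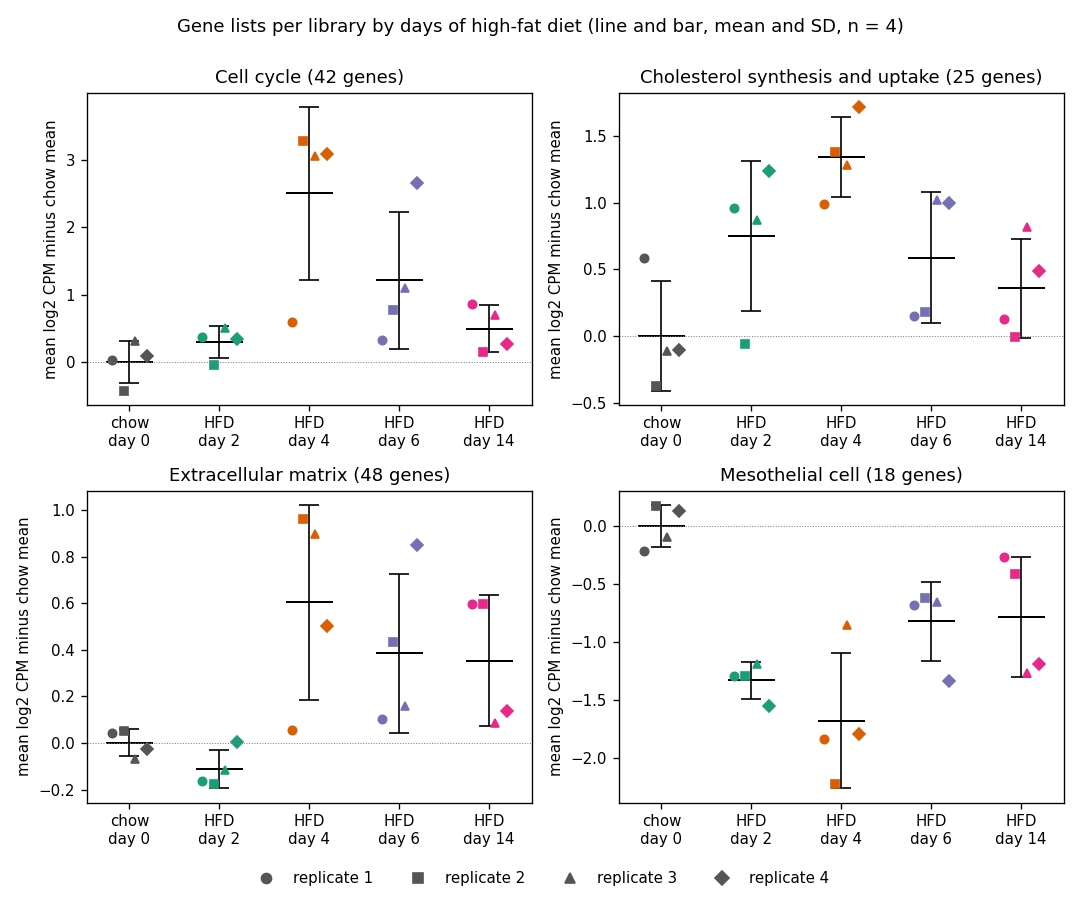
Mean log2 CPM of 4 gene lists minus the chow mean (vertical axes, log2) in each library by days of high-fat diet (horizontal axis). Symbols are the 4 replicates, and the line and bar show mean and SD (n = 4). Day 4 replicate 1 lies at 0.59 for the cell cycle list and the other day 4 libraries at 3.06 to 3.28. Mesothelial means lie below chow on all 4 days, from -1.68 ± 0.59 on day 4 to -0.78 ± 0.52 on day 14.

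After 6 days, Trarg1 went from 338 ± 41.6 to 593 ± 65.5 CPM (SD, n = 4). Its log2 change was 0.81 ± 0.12 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00707), and it kept its call whichever library was left out. Of 66 named genes with a call 64 lost it in at least 1 such fit. Extracellular matrix genes rose in 12 of 48 cases and fell in none (22 and 2 when adjusted over the list alone), including Sparc (0.92 ± 0.20), Col5a2 (0.77 ± 0.15) and Loxl1 (0.65 ± 0.13). With library size only 6 rose and 1 fell, and the matrix mean was 0.85 in day 6 replicate 4 against 0.10 to 0.43 in the rest of the day. Adipose expansion markers rose in 5 of 19 cases (9 rose and 1 fell when adjusted over the list alone), with Mest at 1.87 ± 0.37, Npr3 at 1.06 ± 0.29 and Vldlr at 0.65 ± 0.14. Cell cycle genes lay above chow in 42 of 42 cases with a median of 1.75, of which Nuf2 (2.65 ± 0.70) and Uhrf1 (1.92 ± 0.52) were called over all genes and 32 when adjusted over the list alone. Day 6 replicate 4 had a cell cycle mean of 2.65 against 0.32 to 1.10 in the other 3 libraries of the day. Without it Nuf2 and Uhrf1 had adjusted p = 0.199 and 0.200 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Ribosomal protein genes fell in 10 of 69 cases (39 when adjusted over the list alone, and 40 with library size only), with Rps27 at -0.58 ± 0.11 and Rpl23 at -0.30 ± 0.06. Mesothelial markers had a median of -0.85, with Rspo1 (-1.05 ± 0.24) and Krt18 (-2.37 ± 0.63) called lower, Igfbp5 (0.71 ± 0.18) called higher, and 14 lower and 1 higher when adjusted over the list alone. With library size only 7 mesothelial markers fell and 0 rose. By camera the 5 lists had Benjamini-Hochberg adjusted p = 1.32e-06, 0.00254, 4.75e-11, 4.19e-19 and 7.20e-07, in the order given, with adjusted p = 0.635, 0.0843, 0.749, 0.521 and 0.521 with an estimated correlation. None of their members was called without chow replicate 4 (Mest then had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0966 and Krt18 one of 0.245). All 5 medians kept their sign with library size only, which lowered changes in general and so could have turned only the positive ones. In the same order the medians were 0.57, 0.46, 1.75, -0.21 and -0.85 with all libraries. Without both doubted libraries they were 0.61, 0.39, 1.71, -0.22 and -0.85.

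In total 527 genes differed between day 6 and day 0, 304 higher and 223 lower, and with scaling by library size only 907 differed, 160 higher and 747 lower. The largest rises were Bpifb6 (3.52 ± 0.76), Pimreg (2.99 ± 0.77), Pbk (2.88 ± 0.67), Mup3 (2.79 ± 0.65), Nuf2 and Otop1 (2.62 ± 0.68). Fermt1 had 1 read on day 6 and a ratio of 1003 (95% counting interval 180 to 39650). Further falls were Ppp1r1b (-7.04 ± 1.57), the desmosome gene Dsp (-4.50 ± 1.07), Fndc7 (-4.20 ± 1.02), Ttc16 (-4.09 ± 0.97) and Gprasp2 (-3.97 ± 0.89). Of the 223 lower genes 95 were more than 2-fold higher in chow replicate 4 than in the other chow libraries, Dsp for example at 59.3 against at most 1.44 CPM. Without that library Dsp had an adjusted p = 0.358, Fndc7 one of 0.385 and Fermt1 one of 0.292 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Without day 6 replicate 4 Otop1 had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.226 and Pimreg one of 0.196. The count of 527 was 7 without chow replicate 4, 15 without day 6 replicate 3, 22 without day 6 replicate 4, 27 without day 6 replicate 2, 275 without chow replicate 2, 1099 without chow replicate 1, and 1337 without day 6 replicate 1. It was 3 without both doubted libraries. Camera placed 17 lists past the threshold and none with an estimated correlation.

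After 14 days, Trp53inp2, a regulator of autophagosome formation, stood at 1318 ± 204 CPM against 400 ± 60.3 CPM on chow (SD, n = 4). Its log2 change was 1.72 ± 0.20 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.30e-04). Hr, a nuclear receptor corepressor gene, rose by 2.28 ± 0.33 and Mest by 2.17 ± 0.38. The fructose transporter gene Slc2a5 went from 3.00 ± 2.08 CPM to 1 read in 4 libraries, a ratio of 161 (95% counting interval 28.6 to 6376). In total 180 genes differed, 134 higher and 46 lower, and with scaling by library size only 143 differed, 65 higher and 78 lower. Other large rises were Gabrr2 (2.37 ± 0.55), Paqr9 (1.90 ± 0.38) and the phosphatase gene Dusp10 (1.80 ± 0.44). Other large falls were the acyl-CoA thioesterase gene Acot1 (-3.41 ± 0.76), the acute phase gene Lcn2 (-3.41 ± 0.81), Rassf6 (-3.30 ± 0.77), Rap1gap (-2.73 ± 0.66) and Stard10 (-2.52 ± 0.53). Lcn2 measured 113 CPM in chow replicate 4 and 4.58 to 8.60 CPM in the other chow libraries, and had an adjusted p = 0.246 without it in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Without the same library Rap1gap had an adjusted p = 0.200, Dusp10 one of 0.148, Acot1 one of 0.131 and Paqr9 one of 0.0892, by the same edgeR quasi-likelihood test and Benjamini-Hochberg adjustment. The edgeR call was also lost by Rassf6 (0.119) and Stard10 (0.0891) without day 14 replicate 3, and Gabrr2 (0.102) without day 14 replicate 2, after Benjamini-Hochberg adjustment.

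Ribosomal protein genes lay below chow in all 69 cases on day 14, with a median of -0.23; Rpl3 (-0.40 ± 0.08) and Rpl23 (-0.33 ± 0.06) were called over all genes, 40 when adjusted over the list alone and 10 with library size only. Of 48 matrix genes Sparc (0.96 ± 0.20), Loxl1 (0.85 ± 0.13) and Nid1 (0.62 ± 0.13) rose, or 15 when adjusted over the list alone. The day was divided, with matrix means of 0.60 and 0.60 in replicates 1 and 2 and 0.08 and 0.14 in replicates 3 and 4. Progenitor means were 0.42, 0.43, -0.29 and -0.40 in that order, and mesothelial means -0.27, -0.41, -1.27 and -1.19. No mesothelial marker was called over all genes, and 10 fell and 1 rose when adjusted over the list alone, with a median of -0.73. Of 19 adipose expansion markers Mest alone rose over all genes, and 9 rose and 1 fell when adjusted over the list alone. The ribosomal, matrix, mesothelial and expansion lists had camera Benjamini-Hochberg adjusted p = 7.73e-26, 4.99e-07, 9.93e-07 and 1.29e-04, with adjusted p = 0.381, 0.628, 0.628 and 0.0119 with an estimated correlation. Their medians kept their sign under every scaling. Library size only lowered changes in general, so it could not have turned the negative ribosomal and mesothelial medians. The expansion markers were the only list past the threshold with an estimated correlation among the 12 that camera called. Of 23 genes of fatty acid synthesis 3 fell, or 6 when adjusted over the list alone: Tkt (-1.35 ± 0.22), Acly (-1.90 ± 0.46) and Elovl6 (-1.55 ± 0.37), where camera gave a Benjamini-Hochberg adjusted p = 0.0699. Acly and Elovl6 had adjusted p = 0.120 and 0.126 without day 14 replicate 2, and Sparc, Nid1, Rpl3 and Rpl23 had 0.0892, 0.102, 0.0572 and 0.0664 without chow replicate 4 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 180 was 46 without day 14 replicate 3, 55 without chow replicate 4, 78 without day 14 replicate 2, 111 without chow replicate 2, 470 without chow replicate 1 and 37 without both doubted libraries. Of 36 named genes with a call 13 kept it whichever library was left out, among them Trp53inp2, Trarg1, Hr, Mest, Tkt, Loxl1, Ptpn1, Myo1c and Slc2a5.

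Glucose uptake, insulin signalling and autophagy in adipocytes were the topic of the series. The glucose transporter gene Slc2a4 had log2 changes of 0.11 ± 0.17, -0.18 ± 0.17, 0.07 ± 0.17 and -0.12 ± 0.17 on days 2, 4, 6 and 14, none of them called. Of all tested genes 35.3% were called on day 4, so counts of called members near that share do not mark a list out. Of 24 genes of glucose transport and GLUT4 traffic 3 rose and 7 fell on day 4, by either adjustment, with a median of -0.05 (camera, Benjamini-Hochberg adjusted p = 0.657). On days 2, 6 and 14 that list had 2, 2 and 1 members that rose and none that fell, or 2 and 1 on day 14 when adjusted over the list alone. Without chow replicate 4 edgeR called 0 of them on days 2 and 6. Slc2a1, Irs1, Pparg, Ulk1, Sqstm1, Tfeb, Fasn, Scd1, Sfrp5, Adgre1, Itgax and Tnf were not called on any day. On day 4 the insulin receptor gene Insr fell by 0.42 ± 0.12 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0103), Irs2 by 1.04 ± 0.35 and Adipoq by 0.92 ± 0.31. Irs2 and Adipoq had adjusted p = 0.0852 and 0.0986 without day 4 replicate 4 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of 33 insulin signalling genes 8 rose and 9 fell on day 4, by either adjustment, with Rictor at -0.52 ± 0.10, Foxo3 at -0.75 ± 0.18, Tsc1 at -0.40 ± 0.08 and Ptpn1 at 0.45 ± 0.09 (camera, Benjamini-Hochberg adjusted p = 0.956). With library size only 4 rose and 10 fell, and 11 were called without day 4 replicate 4. On days 2, 6 and 14 that list had 2, 0 and 1 called members, and its medians of 0.09, 0.01 and 0.08 turned to -0.01, -0.12 and -0.02 with library size only. Of 45 autophagy genes 9 rose and 10 fell on day 4, by either adjustment, including Optn (1.17 ± 0.24), Uvrag (0.63 ± 0.13), Gabarapl1 (-0.97 ± 0.19) and Map1lc3b (-0.62 ± 0.18). With library size only 4 rose and 14 fell and the median of 0.03 turned to -0.09, and 10 were called without day 4 replicate 4 (camera, Benjamini-Hochberg adjusted p = 0.873). Map1lc3b had an adjusted p = 0.0529 without day 4 replicate 4 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Map1lc3a rose on all 4 days, by 0.51 ± 0.11 on day 2, 0.36 ± 0.11 on day 4, 0.56 ± 0.11 on day 6 and 0.73 ± 0.11 on day 14. Without chow replicate 4 it had an adjusted p = 0.0764 on day 2 and 0.103 on day 6 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Lep, the leptin gene, rose on all 4 days from 637 ± 228 CPM on chow, by 1.17 ± 0.32, 2.05 ± 0.32, 1.47 ± 0.32 and 1.49 ± 0.32. On days 2, 6 and 14 leaving out 1 library ended its call 5 times each, with the highest adjusted p = 0.175 without day 2 replicate 4, 0.105 without day 6 replicate 4 and 0.0988 without day 14 replicate 3 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The chemokine gene Ccl2 rose on day 4 by 2.95 ± 0.67, and its changes of 2.21 ± 0.65 on day 6 and 2.14 ± 0.66 on day 14 were not called.

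**Figure D3:**
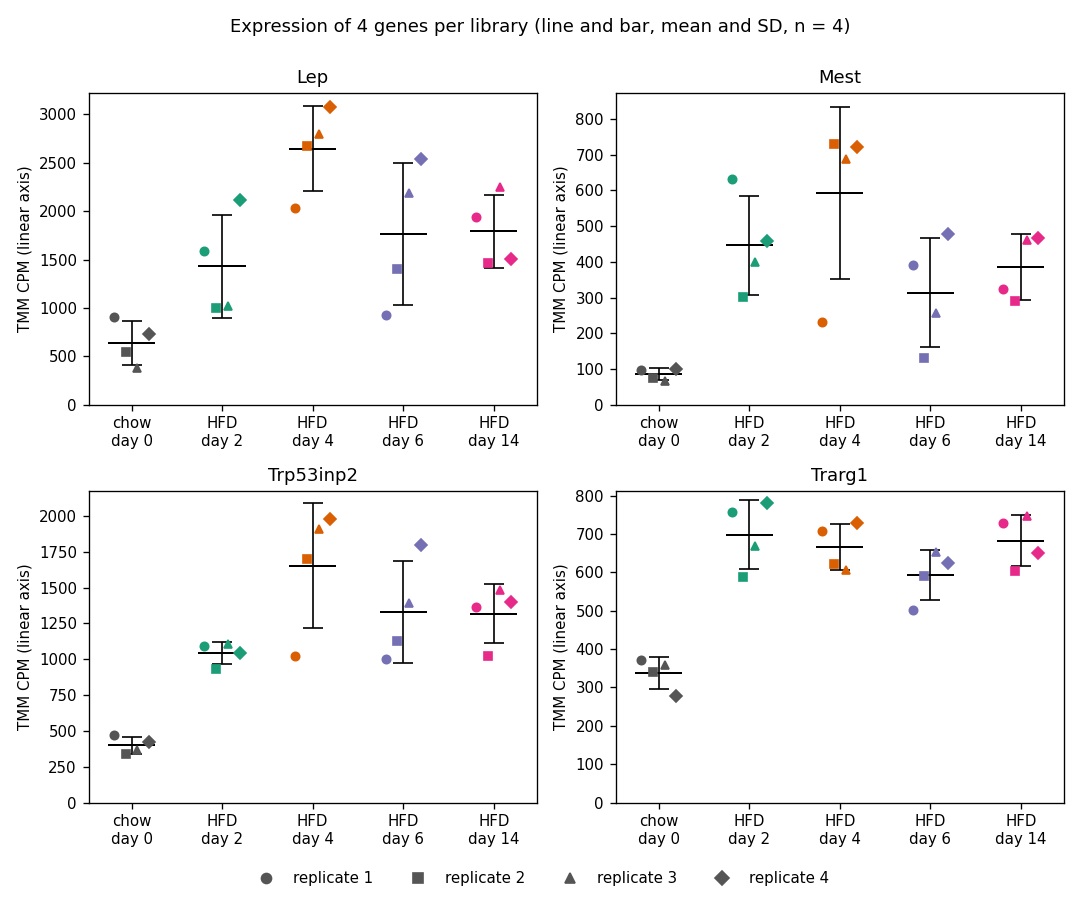
Expression of Lep, Mest, Trp53inp2 and Trarg1 (vertical axes, TMM CPM, linear from 0) in each library by days of high-fat diet (horizontal axis). Symbols are the 4 replicates, and the line and bar show mean and SD (n = 4). Trp53inp2 lies at 337 to 473 CPM in the chow libraries and at 934 to 1978 CPM in the high-fat libraries.

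A test of any difference among the 5 groups called 2994 of 15254 genes. Among its smallest p were those of Trp53inp2 (log2 changes 1.38, 2.05, 1.73 and 1.72 on days 2, 4, 6 and 14) and the keratin gene Krt79 (1.83, 2.06, 2.04 and 1.65), each with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.00149. Trarg1, Rhbdf1, Slc6a13, Alas1 and Ramp2 followed with rises on each day, and Cobl and Stk26 with falls. Called on all 4 days against chow were 69 genes, 49 that rose and 20 that fell. Of these Krt79, Trp53inp2, Trarg1, D430019H16Rik and Ehd2 kept all their calls whichever library was left out, and Krt79 and Trp53inp2 also without both doubted libraries. The count of 2994 was 972 without day 4 replicate 4, 1471 without chow replicate 4, 1492 without day 4 replicate 2, 1644 without day 4 replicate 3, 1847 without chow replicate 2, and 1937 without chow replicate 3. It was 773 without both doubted libraries.

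Between days 2 and 4, edgeR called 327 genes higher and 39 lower on day 4. Of 42 cell cycle genes 39 rose, or 42 when adjusted over the list alone, and so did 11 of 48 matrix genes, or 30 when adjusted over the list alone. The largest rises were the mitotic genes Melk (3.70 ± 0.77), Hmmr (3.68 ± 0.75), Aspm (3.50 ± 0.74) and Spag5 (3.43 ± 0.75), each with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0412 (SE, n = 4). The largest falls were Cd63-ps (-1.56 ± 0.39), Rasl11a (-1.52 ± 0.32), Phf24 (-1.48 ± 0.37) and the coagulation gene F3 (-1.31 ± 0.28). Each of these 8 genes lost its call in 6 of the 8 fits without 1 library, with Melk at an adjusted p = 0.165 without day 2 replicate 2 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 366 was reached by 3 of 35 splits of the same 8 libraries, the real one included. It was 0 with library size only, 0 without a filter and 0 in a fit of only the 2 groups. It was 0 as well without both doubted libraries (edgeR; 3406 genes at an unadjusted p under 0.05 with all libraries, and 912 by DESeq2, 0 by limma-voom and 3394 with quality weights). It was also 0 without any 1 of 6 of the 8 libraries compared, 589 without day 2 replicate 4 and 2251 without day 4 replicate 1. Between day 4 and day 6 edgeR called 0 genes, with 2492 at an unadjusted p under 0.05, while DESeq2 called 53, limma-voom 0 and limma-voom with quality weights 2046. DESeq2 gave no adjusted p for 14195 of the 15254 genes in this comparison. The edgeR count was 785 without day 4 replicate 1 and 432 without day 6 replicate 4. Between day 6 and day 14 edgeR called 0 genes, with 508 at an unadjusted p under 0.05, and DESeq2 and limma-voom with and without weights called 0. Between day 2 and day 14 edgeR called 0 genes, with 1847 at an unadjusted p under 0.05, while DESeq2 called 134, limma-voom 0 and limma-voom with quality weights 1160. Without day 14 replicate 4 the edgeR count was 20, without day 2 replicate 2 it was 8 and without day 14 replicate 3 it was 1.

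Changes against chow were related across days. Across genes, which are not independent replicates, log2 changes of days 4 and 6 correlated at 0.89 and those of days 6 and 14 at 0.86. In these pairs 285 and 81 genes were called higher and 217 and 32 lower on both days. No gene was called in opposite directions in any of the 6 pairs of days. The pairs of day 2 with days 4, 6 and 14 had 0.74, 0.77 and 0.74, and days 4 and 14 had 0.75. All 4 comparisons used the same chow libraries, and simulated unchanged groups against them gave 0.44 to 0.47. Independent lists of the same sizes would share 54.6 higher and 38.6 lower genes between days 4 and 6, and 2.67 and 0.672 between days 6 and 14. With the chow libraries split 2 and 2, a median of 27 higher and 32.5 lower genes was shared between days 4 and 6, and 4 and 0 between days 6 and 14. Single splits gave 1 to 179 higher genes for days 4 and 6. These medians come from other lists, called against 2 chow libraries each, so the numbers for independent lists above do not apply to them. The covariance was 0.513 for days 4 and 6 against 0.0462 in the simulation, and 0.316 for days 6 and 14 against 0.0448. In single fits with split controls it was 0.266 to 0.302 for days 4 and 6, and 0.0844 to 0.122 for days 6 and 14. The simulation drew each gene on its own, so no simulated chow library stood apart as chow replicate 4 did. It therefore understates what the shared chow libraries add. With the chow libraries split 2 and 2 the mean correlations were 0.54 for days 4 and 6, 0.31 for days 6 and 14 and 0.15 for days 2 and 14.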

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

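The tests of exchanged labels, of timing between animals and of epididymal or ciliated tissue were chosen only after the results were seen, those on depth by thinning were chosen after seeing the data but before their own values, and those on other splits of the libraries were fixed earlier. In 335 sets of 4 libraries, Dixon's ratio (the gap of 1 library to its nearest neighbour over the whole range) was past its critical value in 30, where chance gives about 1 in 20, or 16.8. Day 4 replicate 1 had 7 of them, chow replicate 4 had 4, and the others had at most 3 each.

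Cell cycle genes set day 4 replicate 1 apart from the other day 4 libraries (ratio 0.917), with a list mean of 0.59 against 3.06 to 3.28, and day 6 replicate 4 had 2.65 against 0.32 to 1.10 in the rest of its day. Depth was argued against, since with all libraries thinned to the same total the gap on day 4 was still 2.20. An exchange of these 2 labels may explain it: over 15212 genes without the cell cycle list, day 4 replicate 1 correlated at 0.76 with day 6 and 0.67 with its own day, a gain of 0.0914, and day 6 replicate 4 at 0.90 with day 4 and 0.71 with its own. A difference between animals in the timing of cell division was not decided, since 5 of the 12 libraries of days 2, 6 and 14 had cell cycle means between day 4 replicate 1 and the rest of day 4, but 1 of them was day 6 replicate 4 itself and the other 4 lay at 0.70 to 1.10. The correlations cannot separate the 2 explanations. Other genes of cell division, and matrix genes that also set these libraries apart, stayed among the 15212. A difference in timing could give the same correlations. Both explanations stay open.

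Ductal epithelium genes set chow replicate 4 apart, by the list of epididymis and vas deferens (ratio 0.848, mean 1.62 against -0.69 to -0.34), and depth was argued against, since after thinning the gap to the next chow library was still 1.33. Of 28 epididymis genes with counts 10 were highest of all 20 libraries there, and 3 of the list reached 1 CPM in the other chow libraries. Cuzd1 had 79.7 CPM against 0.0472 (scaled here to the counts of all genes, before the filter) and Aqp9 14.9 against 2.41. Clu had 134 against 146 and Sult1e1 53.8 against 57.8. Both genes were already that high in the other chow libraries, so they could not reveal a small admixture. Epididymal tissue is neither excluded nor shown. Of 21 genes of multiciliated cells, a list written after the data were seen, 20 were highest there, 2 of the list reached 1 CPM in the other chow libraries, and Cfap44 had 75.4 CPM against 0.264, Cfap65 61.8 against 0 and Dnah11 37.1 against 0. Tppp3 had 60.4 against 40.8 and up to 93.6 elsewhere, too high in other libraries to reveal an admixture. Because that list was written from the pattern itself, multiciliated epithelium taken along at dissection stays open without being shown, and no biological explanation was tested.

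Chow replicate 1 and day 2 replicate 2 lay closer together than their groups, with fatty acid synthesis list means of 0.52 and -0.46 against -0.28 to -0.05 and 0.23 to 0.39 in the rest of their groups, and Fasn set day 2 replicate 2 apart at a log2 CPM of 11.19 against 13.27 to 13.43 (ratio 0.930). On 274 genes called on days 4, 6 and 14 in a fit without chow replicate 1 and day 2, day 2 replicate 2 lay nearer the high-fat mean in 71.2%, the other day 2 libraries in 84.3 to 91.6%, chow replicate 1 in 56.2% and the other chow libraries, which had helped to choose the genes, in 0.365 to 9.85%. With chow replicates 2, 3 and 4 also left out in turn (271, 427 and only 39 genes), the left-out library lay nearer the high-fat mean in 52.4%, 56.7% and 15.4%, chow replicate 1 in 73.4%, 77.0% and 56.4% and day 2 replicate 2 in 74.9%, 80.8% and 89.7%. The lowest of the other day 2 libraries had 79.7%, 81.0% and 89.7%, so these percentages do not decide on an exchange of labels. Mesothelial list means argue against it, with -0.21 in chow replicate 1 against -0.09 to 0.17 in the other chow libraries. Day 2 replicate 2 had -1.29 against -1.55 to -1.19 in the rest of its day. The fatty acid synthesis means above go the other way. The bound was rewritten after values were seen: a first version would have counted chow replicate 1 in favour of an exchange, and a later one, which asked only for 50% in day 2 replicate 2, against it. No biological explanation was tested for this pattern.

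Chance was tested by refitting other splits of the same libraries. Among 35 splits of 8 libraries, only the real one (1) reached the real count against day 0 on day 4 (5381 genes, highest other split 1331), day 6 (527, 33) and day 14 (180, 1). That argues against chance there without excluding it. A share of 1 in 35 is the smallest that such splits can give, and these comparisons use the same chow libraries. Chance was also argued against for any difference among the 5 groups (2994 genes, highest other split 977), where 1 of 100 drawn splits, the real one, reached that count. For day 2 against day 0 chance was not excluded: 2 of 35 splits reached 670, with 1054 when chow replicate 1 and day 2 replicate 2 changed places. The difference between days 4 and 2, in 366 genes, was reached by 3 of 35 splits, so chance was not excluded, and 1890 genes came with day 2 replicate 4 and day 4 replicate 1 in each other's place. For day 6 against 4, day 14 against 6 and day 14 against 2, edgeR called 0 genes (2492, 508 and 1847 at an unadjusted p under 0.05). DESeq2 called 53, 0 and 134 there, with no adjusted p for 14195, 126 and 421 of 15254 genes, limma-voom 0 in each, and limma-voom with quality weights 2046, 0 and 1160. A real count of 0 is reached by every split, so that 35 of 35 says nothing about chance there, and the highest other splits had 2489, 7 and 158. The 2489 came from exchanging day 4 replicate 1 with day 6 replicate 4. Splits with more genes than the real one point to a structure of the samples beyond their groups.

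Other libraries set apart by a list mean or gene were these, with the ratio. In chow replicate 4 they were the TMM factor of 1.17 against 1.02 to 1.04 (0.858), insulin signalling (0.857) and fatty acid uptake (0.907). In chow replicate 2 it was the unfolded protein response (0.903) and in chow replicate 1 it was the circadian clock (0.832). On day 2 they were adipocyte progenitor genes in replicate 2 (0.917), T and NK cell genes in replicate 1 (0.853) and Itgax in replicate 4 (0.855). In day 4 replicate 1 they were glucose transport (0.857), branched-chain amino acid catabolism (0.853), NRF2 targets (0.884), B cell genes (0.847), Ulk1 (0.887) and Mest at a log2 CPM of 7.85 against 9.43 to 9.51 (0.951). Day 4 replicate 2 stood apart in testis genes (0.850) and replicate 4 in Adgre1 (0.900). On day 6 they were glycolysis in replicate 3 (0.871), B cell genes and Npr3 in replicate 1 (0.918 and 0.834), and in replicate 4 Insr (0.909), Irs1 (0.928) and mesothelial genes at -1.33 against -0.68 to -0.62 (0.919). On day 14 they were the interferon and unfolded protein responses in replicate 4 (0.898 and 0.966), smooth muscle and B cell genes in replicate 1 (0.901 and 0.830) and testis genes in replicate 3 (0.831).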

How the results depend on the processing

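Leaving out both doubted libraries and thinning all libraries to the smallest total of 1916829 counts were tests chosen after seeing the data, and the other alternatives were fixed earlier. Counts of genes for days 2, 4, 6 and 14 against day 0 stayed within 1.5 times their main values of 670, 5381, 527 and 180 with DESeq2's size factors in edgeR (705, 5335, 506 and 179) and with a stricter filter (735, 4785, 427 and 206). So did the number of lists with a prior count of 0.5 (14, 9, 17 and 12). The day 4 count also stayed within that range under library size only, no filter, DESeq2, limma-voom with and without weights, a fit of the 2 groups, the library number and without both doubted libraries.

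The other counts moved as follows, and the cause was not tested unless said. Library size only gave 907 genes on day 6 and 0 between days 4 and 2. No filter gave 317 on day 2, 130 on day 6, 96 on day 14 and 0 between days 4 and 2, with more genes to adjust for. DESeq2 gave 1412 on day 2, 1180 on day 6, 659 on day 14, 912 between days 4 and 2, 53 between days 6 and 4 and 134 between days 14 and 2. Its adjusted p was missing for 126 to 717 of 15254 genes on days 2 to 14 against day 0, for 421 between days 14 and 2 and for 14195 between days 6 and 4, so that the 53 rest on the few genes left. Limma-voom gave 444 on day 2 and 0 between days 4 and 2. With quality weights it gave 1244 on day 2, 1045 on day 6, 565 on day 14, 3394 between days 4 and 2, 2046 between days 6 and 4, 1160 between days 14 and 2 and 6386 for any difference. The lowest weights were 0.355 for day 4 replicate 1, 0.433 for chow replicate 4 and 0.504 for day 6 replicate 4. Leaving out day 4 replicate 1 also raised the edgeR counts, to 2251 between days 4 and 2 and 785 between days 6 and 4. Leaving out day 6 replicate 4 gave 432 between days 6 and 4. A fit of only the 2 groups, with fewer libraries to estimate dispersion, gave 165 on day 2, 0 on day 6, 74 on day 14, 0 between days 4 and 2 and 1 between days 14 and 2. The library number as a covariate gave 296 on day 2, 177 on day 6, 1261 between days 4 and 2 and 3 between days 6 and 4.

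Without both doubted libraries the counts were 8 on day 2, 3 on day 6, 37 on day 14, 0 between days 4 and 2 and 773 for any difference. Thinning gave 400 on day 2, 2805 on day 4, 98 on day 6, 75 on day 14, 138 between days 4 and 2, 1 between days 14 and 2 and 1391 for any difference, which is what depth limits here. Thinning also reversed Cd3e on day 4, from -1.36 to 0.73. An added bound on the absolute log2 change of 1 left 233, 1735, 210 and 64 genes on days 2, 4, 6 and 14, 231 between days 4 and 2 and 1311 for any difference. An adjusted p under 0.01 left 39, 2635, 11, 37, 0 and 445, by construction fewer. With 1 library left out the counts ranged from 43 to 1779 on day 2, 3225 to 5698 on day 4, 7 to 1337 on day 6 and 46 to 470 on day 14. Between high-fat days they ranged from 0 to 2251 between days 4 and 2, 0 to 785 between days 6 and 4 and 0 to 20 between days 14 and 2. For any difference they ranged from 972 to 4012. Calls against day 0 had the same sign in each of these fits except without chow replicate 4, where 5357 of 5381 did on day 4 and 523 of 527 on day 6.

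With a correlation estimated from the data camera called 0, 0, 0 and 1 lists on days 2, 4, 6 and 14, and fry called 1, 7, 3 and 2, against 14, 9, 17 and 12. With 1 library left out, 11 to 19 lists passed on day 6. Correlations between log2 changes, with the chow libraries split 2 and 2, were 0.33 for days 2 and 4, 0.23 for days 2 and 6, 0.15 for days 2 and 14, 0.54 for days 4 and 6, 0.34 for days 4 and 14 and 0.31 for days 6 and 14. The comparisons then had no chow library in common.

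The replicate number as a block gave 551 genes between days 4 and 2 and 32 between days 14 and 2, and the other counts stayed within 1.5 times. The pairing was checked by correlation of residuals: 12 of 40 pairs of libraries with the same number exceeded 0.1, with a median of 0.04 against -0.01 for different numbers. Of the 20 libraries 10 correlated best with a library of the same number, and the number expected by chance was not worked out. The highest value, 0.52, joined replicates 1 of days 4 and 6. Day 4 replicate 1 and day 6 replicate 4, each set apart from its own day, had -0.69. Both shift their group means, so the 0.52 cannot be read as a shared origin. Since not every pair exceeded 0.1, the numbers were not used as pairs. That rule is strict, and missing it does not show that libraries of the same number are unrelated. The library numbers of replicates 3 and 4 form separate runs, 21 to 25 and 26 to 30. Some shared origin or order of handling stays possible.

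Of the values of named genes, 390 kept their side of the threshold after thinning and 116 lost their call, 335 and 175 without both doubted libraries, and 478 and 16 with DESeq2. Direction was checked only for values with a call. These numbers were 469 and 35 with library size only, 354 and 155 in a fit of the 2 groups and 3225 and 827 over all fits without 1 library. Of list results over the fits without 1 library, 1206 were the same, 55 lost and 51 gained a call.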

Other observations

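The tests on the lower mesothelial markers were chosen only after the result was seen.

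Genes of several lists changed after 4 days of high-fat diet, when 35.3% of all tested genes were called. The metallothionein genes Mt1 (log2 change -1.66 ± 0.29, SE, n = 4) and Mt2 (-2.34 ± 0.48) fell, as did Gpx3, which encodes a secreted glutathione peroxidase (-2.16 ± 0.40). In their list of 30 oxidative stress genes 6 rose and 13 fell (6 and 14 when adjusted over the list alone), and the list was not past the threshold (camera, Benjamini-Hochberg adjusted p = 0.136, and 0.898 with an estimated correlation). With library size only 3 rose and 15 fell, and 10 were called without day 4 replicate 2. Txnip, a glucose-responsive inhibitor of glucose uptake, fell from 1377 ± 709 to 277 ± 86.3 CPM (SD, n = 4; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00173). Pck1 (-1.99 ± 0.36) and the adrenergic receptor gene Adrb3 (-1.28 ± 0.30) fell. The lipid droplet gene Hilpda (1.63 ± 0.27), Fabp5 (2.04 ± 0.33) and the peptide hormone gene Apln (2.70 ± 0.57) rose. Dio2 (4.38 ± 0.78), Otop1 (4.04 ± 0.70) and Cox7a1 (2.31 ± 0.35) rose among 12 genes of thermogenic adipocytes, where 1 fell, with levels of 6.50 to 9.09 CPM on day 4 (camera, Benjamini-Hochberg adjusted p = 0.387). The chemokine gene Ccl7 (2.67 ± 0.57) and S100a8 (2.30 ± 0.56) rose, while Il33 (-1.72 ± 0.29) and the neutrophil protease gene Elane (-3.84 ± 0.78) fell. Of 33 inflammatory genes 5 rose and 5 fell, and of 13 neutrophil and mast cell genes 1 rose and 2 fell, by either adjustment (camera, Benjamini-Hochberg adjusted p = 0.879 and 0.225). All of the named genes kept their call whichever single library was left out and without both doubted libraries.

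Some lists were past the threshold on other days with few called members. Of 40 interferon response genes 1 rose on day 2, with a median of -0.22 (camera, Benjamini-Hochberg adjusted p = 0.00211, with adjusted p = 0.679 with an estimated correlation). With library size only 0 rose and 1 fell, and edgeR called 0 of them without chow replicate 2 or chow replicate 4. Of 29 immediate early genes none was called by edgeR over all genes on day 2 (median -0.35) or on day 14 (median 0.31, 8 rose when adjusted over the list alone). Camera gave Benjamini-Hochberg adjusted p = 0.0324 and 1.38e-04, with adjusted p = 0.679 and 0.628 with an estimated correlation. The immediate early means of day 14 were 0.72, 0.68, -0.10 and 0.33 in replicates 1 to 4. Of 25 adipocyte identity genes 2 rose on day 14, with a median of 0.19 (camera, Benjamini-Hochberg adjusted p = 0.00176, with adjusted p = 0.628 with an estimated correlation), and 1 was called without chow replicate 2. These medians kept their sign with library size only, which lowered changes in general and so could not have turned the negative ones.

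Mesothelial markers fell on days 2 and 4 by the medians given above, and 2 explanations were tested. A lower share of all cells other than adipocytes may lower such markers, but on day 2 the mesothelial mean differed from that of the macrophage list by -0.90 (log2, pooled SD 0.41). It differed from the progenitor, endothelial and smooth muscle lists by -0.94, -1.37 and -1.33, and these gaps argue against that explanation. Ductal epithelium in chow replicate 4 was argued against as well, since 92.8% of the median change on day 2 stayed without that library. Less mesothelium in the samples, by dissection or by diet, stays open and was not tested.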
